A study of Mus musculus with 4 samples.

How the data were processed

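ATAC-seq libraries were made from CD4+ FOXP3+ Tregs of mouse spleen, in 2 samples from vehicle-treated and 2 from venetoclax-treated mice (50 mg/kg, 14 days). Per the labels' protocols, cells were lysed, nuclei were transposed with an Illumina tagmentation enzyme and libraries were indexed with a Nextera kit. Bowtie2, Picard and MACS2 and the mouse build mm10 are named in the submitters' processing notes, without versions or the role of each. The file the authors deposited holds a chromVAR deviation score per motif and sample, per the file's name, together with group means, their difference and a rank. How reads were shifted or filtered, the peak set, the background peaks, the motif collection and the chromVAR version are not given in the sources used here. Whether the score is a z-score or a bias-corrected deviation is not stated. The values of both signs with an SD per sample from 0.89 to 0.97 were treated as z-scores. A chromVAR score is relative to the samples scored together, which affects correlations between samples. Which samples were scored together is not given, so the direction of that effect is unknown. The table has 12 sample columns, of which 8 do not match a sample described in the labels and were not used. No read counts or depths were used, so the depth per sample is unknown and no counting interval could be given. The precision rests on the spread between the samples, shared over motifs.

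The table holds 1346 motif entries for 796 transcription factor symbols, with 976 distinct sets of 4 scores. Symbols were matched to RefSeq gene names of assembly GRCm38.p6, used for names only. Of the entries, 1229 matched by symbol, 45 by an older symbol and 24 by a protein accession, and 48 did not match. No peak coordinates were used. The authors' deposited differences equalled those computed here within 1e-09.

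Scores were tested as deposited, with no log, pseudocount or filter. The venetoclax and vehicle samples were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 1346 motifs and a threshold of 0.05 on the adjusted p. Differences are venetoclax minus vehicle in score units, with the moderated standard error and 95% interval. Sharing the spread over motifs gave 21.0 degrees of freedom, of which 2 came from the samples of a motif. Motif families were tested with camera of limma, two-sided, with the correlation between motifs estimated from the residuals. Of 36 lists of transcription factors, 34 had at least 3 motifs and were tested, with adjustment over the 34. The Ctcf motif differed by -0.82 (SE 0.79) and the Ctcfl motif by -2.16 (SE 0.80) in the first untested list, and Nfya by 1.14 (SE 0.71) in the second. List means per sample were compared with an exact permutation test, two-sided. Samples were compared by Pearson correlation across motifs, described without p-values.

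The tests, the lists, the alternatives and the rule for naming motifs were fixed before the data were examined. The rule named 10 motifs per direction past the threshold with non-overlapping groups, 1 motif per symbol with the largest absolute difference, filled by unadjusted p when fewer passed. It also named up to 4 members of each list discussed and a set of 23 factors of T cells and other blood lineages. As no motif passed, all 20 of the first kind were filled by unadjusted p, and the members shown for a list are those furthest from 0. A motif that the rule names and a list that holds it are not reported here. A first exploratory fit of the same test, which gave 0 motifs past the threshold and 246 at an unadjusted p, the sample correlations, the block and the splits, preceded the final one. Chosen after values had been seen were the share of motifs at an unadjusted p as a result in its own right, reported because the planned count was 0, and its expression as a percent in place of a count. The comparison of list medians relative to all motifs was chosen after raw medians had changed sign 45 times over the alternatives. The matching by older symbols and protein accessions, 17 further lists and 2 further alternatives were also chosen then.

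Alternatives were the replicate number as a block, each sample left out, centring, division by the SD, quantile normalization, a minimum SD of 1, 1 value per symbol, 1 entry per distinct set of scores, a trended and robust variance, an ordinary linear model, other thresholds, a preset correlation of 0.01 and the fry test. A test of bias-corrected deviations was not run, since the table has a single kind of score. With a score assumed to have an SD of 1 in every sample, a normal test was also run.

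The limma step was tested on simulated scores for this comparison (1346 motifs, 200 changed), with the spread of the real fit. It recovered 39.6% of motifs changed by 2 score units, 83.7% by 3, 98.2% by 4 and 100% by 6, with 3 false among 165 calls. These rates hold for the simulated setting only, since the adjusted threshold is easier to pass when 200 motifs change. In the real fit the Foxo1 motif, at a difference of -3.80, did not pass (limma adjusted p = 0.0664). With 3 lists shifted by 3 units, camera with an estimated correlation recovered 0 after adjustment, although all 3 had an unadjusted p under 0.05. The preset correlation recovered 3 and called 0 others, and fry recovered 3 and called 1 other.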

Results

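Chromatin accessibility was measured by ATAC-seq, which reads out the DNA that a transposase can reach in nuclei, in CD4+ FOXP3+ regulatory T cells (Tregs) taken from mouse spleen. The mice carried GFP behind Foxp3, the gene of the transcription factor that defines Tregs. They received vehicle or venetoclax, a small-molecule inhibitor of the anti-apoptotic protein BCL-2, at 50 mg/kg for 14 days. There were 2 vehicle samples and 2 venetoclax samples. The labels call them biological replicates without tying each to an animal, so the p-values measure the spread between these samples. The values were the authors' chromVAR deviation scores for 1346 transcription factor motifs. A positive score means that peaks holding the motif were more accessible in that sample than the method's background expectation, and a negative score means less. The scores carry no unit and no read counts, so the depth of each sample is unknown. A score belongs to a sequence motif, not to the expression or binding of the factor it is named for. Related factors share motifs, and 370 of the 1346 motif entries repeated the 4 scores of another entry.

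The first comparison asked whether motif accessibility in splenic Tregs differed between venetoclax and vehicle. The motif shared by Thrb and Thra, the thyroid hormone receptors, had a positive difference. Its score was -1.50 ± 0.67 with vehicle and 1.19 ± 1.22 with venetoclax (SD, n = 2 each), a difference of 2.70 (SE 0.75, limma adjusted p = 0.15). The Foxo1 motif had the largest negative difference. Foxo1 maintains resting T cells and is needed for Treg function. Its score was 2.73 ± 0.31 with vehicle and -1.07 ± 2.22 with venetoclax (SD, n = 2 each), a difference of -3.80 (SE 0.84, limma adjusted p = 0.0664). Neither motif passed the threshold of 0.05. In each the groups did not overlap, but the rule that named these motifs required this. With each sample left out in turn the difference ranged from 1.83 to 3.56 for Thrb and from -5.37 to -2.23 for Foxo1, both nearest to 0 without venetoclax replicate 2. The motifs of the related factors Foxo3 and Foxo4 had smaller differences, of -1.04 and -0.23.

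No motif of the 1346 passed an adjusted p of 0.05 in limma, and 246 had an unadjusted p under 0.05, of which 86 were higher and 160 lower with venetoclax. Chance alone gives 67.3 such motifs, but motifs are not independent. The groups did not overlap for 48.3% of motifs, where chance gives 33.3%. The count of 0 depended on the variance model and on venetoclax replicate 1. With a mean-dependent and outlier-robust variance limma called 74 motifs (48 lower, 26 higher), and without venetoclax replicate 1 it called 337. The latter fit assumes that the remaining venetoclax sample varied like the vehicle samples.

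None of the motifs higher with venetoclax passed the test. Beside Thrb and Thra, the motif shared by the orphan receptors Nr5a2, Esrrg and Nr5a1 differed by 2.30 (SE 0.69). The motif of Trp63, a p53 family member, differed by 2.63 (SE 0.73), and the motif of Fosb, an AP-1 subunit, by 2.59 (SE 0.76). The motifs of Myb, a regulator of blood cell progenitors, and Myf5, a muscle bHLH factor, differed by 2.42 (SE 0.74) and 2.37 (SE 0.68). Each of these motifs had a limma adjusted p of 0.15. With a sample left out the difference ranged from 1.77 to 3.49 for Trp63, from 1.48 to 3.71 for Fosb and from 1.56 to 3.29 for Myb, nearest to 0 without venetoclax replicate 2. For Nr5a2 it ranged from 1.92 to 2.68 and for Myf5 from 2.22 to 2.52. Several of these factors had other motifs with smaller differences, from 0.21 for Trp63, from -0.18 for Thrb and from -0.87 for Myf5.

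Forkhead motifs were among those with the largest negative differences, none of which passed the test. The Foxa1 motif differed by -3.76 (SE 0.96), the motif shared by Foxf2 and Foxf1 by -3.61 (SE 0.80) and the Foxa2 motif by -3.43 (SE 0.81). Foxa1 and Foxa2 are pioneer factors of endoderm. The Foxa1 score was 2.98 ± 0.28 with vehicle and -0.79 ± 3.09 with venetoclax (SD, n = 2 each), so the venetoclax samples differed from each other by more than the vehicle samples did. For Foxa1 and Foxo1 the limma SE is smaller than their own samples would give, since it is drawn toward the spread of other motifs. The motif of Cxxc1, which binds unmethylated CpG, differed by -3.57 (SE 0.83). The motif of Pitx1, a homeodomain factor, differed by -3.31 (SE 0.82). Smaller negative differences were found for the motifs of Hoxb9 (-2.89, SE 0.77), the pseudogene entry Obox3-ps8 (-2.79, SE 0.80) and Zic4 (-2.45, SE 0.70). The limma adjusted p of these negative differences ranged from 0.0664 for Foxf2 to 0.15 for Zic4. Without venetoclax replicate 2 each was nearest to 0, at -1.58 for Foxa1, -2.24 for Foxf2, -2.01 for Foxa2, -2.13 for Cxxc1, -2.18 for Pitx1, -1.81 for Hoxb9, -1.66 for Obox3-ps8 and -1.96 for Zic4. The 13 motifs of Hoxb9 ranged from -2.89 to 0.74.

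**Figure D1:**
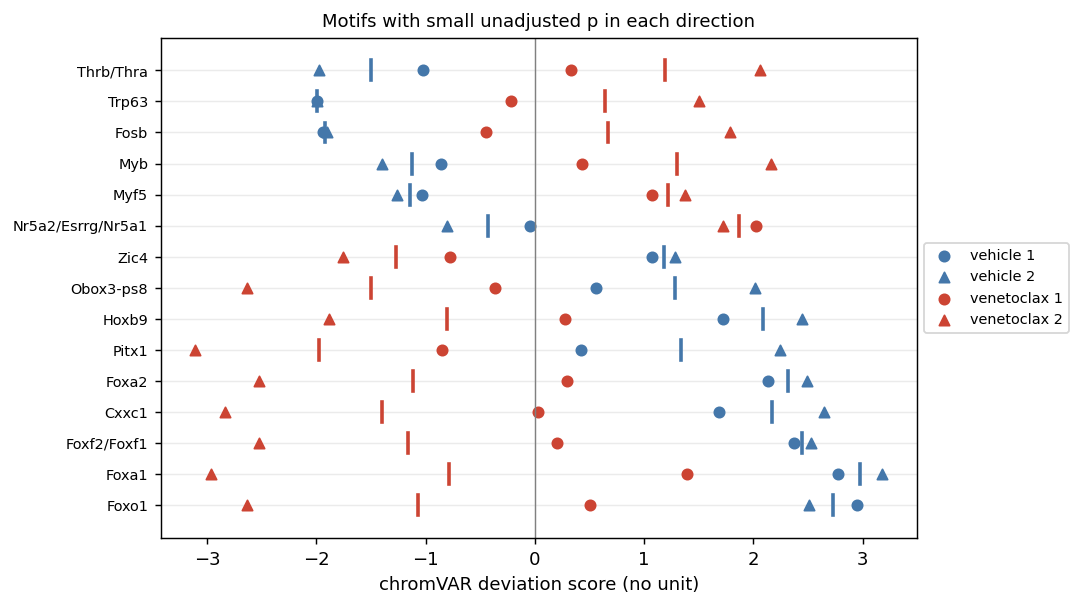
Deviation scores (no unit, horizontal axis) of the motifs named for their small unadjusted p in each direction (vertical axis), with circles for replicate 1, triangles for replicate 2, vehicle in blue, venetoclax in red and a bar at each group mean. For Foxo1 the vehicle samples were at 2.95 and 2.51 and the venetoclax samples at 0.50 and -2.64; no motif shown passed the adjusted threshold.

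Motifs of factors central to Tregs did not pass the test. The Foxp3 motif, shared with Foxp4, scored 0.70 ± 0.38 with vehicle and -0.85 ± 1.41 with venetoclax (SD, n = 2 each). The difference was -1.55, with a 95% interval from -3.11 to 0.02. The motif of Irf4, which directs effector Treg differentiation, differed by -2.16 (SE 0.81, limma adjusted p = 0.178). The motif of Gata3, a Th2 factor also used by tissue Tregs, differed by -1.77 (SE 0.88). The motifs of Stat5a and Stat5b, which act downstream of IL-2, differed by -1.50 (SE 0.72) and -0.51 (SE 0.71). Differences were -1.36 for Nfkb1 (SE 0.69), 0.30 for Rela (SE 0.69), 1.12 for Batf (SE 0.70) and -0.83 for Nfatc1 (SE 0.69). The 3 motifs of Batf ranged from -0.88 to 1.12. The motifs of Runx1 (0.40, SE 0.70), Bach2 (0.11, SE 0.69) and Tbx21 (0.04, SE 0.69) were close to 0. Without vehicle replicate 1 these differences were of the opposite sign, which was also true of Bach2 and Tbx21 without venetoclax replicate 2. Stat5b and Rela changed sign without vehicle replicate 2. The groups overlapped for Gata3, Stat5b, Rela, Runx1, Bach2 and Tbx21. With each sample left out in turn, the difference ranged from -3.23 to -0.31 for Gata3, from -3.38 to -0.94 for Irf4 and from -2.54 to -0.55 for Foxp3, nearest to 0 without venetoclax replicate 2. It ranged from -2.26 to -0.74 for Stat5a, nearest to 0 without vehicle replicate 2, and from 0.64 to 1.60 for Batf, nearest to 0 without vehicle replicate 1. It ranged from -1.69 to -1.02 for Nfkb1 and from -1.02 to -0.63 for Nfatc1.

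Motifs of resting T cell factors gave no common direction. The motif of Klf2, a Foxo1 target that controls T cell trafficking, differed by -1.70 (SE 0.78), with the same scores as Klf3 and Klf6. The 6 motifs of Klf2 ranged from -1.70 to 0.47, and the Klf2 motif at -1.70 ranged from -2.67 to -0.73 with each sample left out in turn, nearest to 0 without vehicle replicate 2. The motifs of Tcf7 and Lef1, the Wnt pathway factors of naive T cells, differed by 0.70 (SE 0.69) and -0.59 (SE 0.74). The second Tcf7 motif differed by -0.54, and Lef1 changed sign without venetoclax replicate 2. The Ets1 motif of largest difference was at 0.97 (SE 0.69) and another at -0.35. The Trp53 motif of largest difference, of interest because p53 controls apoptosis genes, differed by 1.00 (SE 0.74), with other Trp53 motifs down to -0.50. The Ctcf motif differed by -0.82 (SE 0.79), with the opposite sign without venetoclax replicate 2. Among factors of other blood lineages, Spi1 differed by -2.15 (SE 0.68) in 1 motif and -0.086 in another, Cebpb by 1.53 (SE 0.75) and Ebf1 by 0.45 (SE 0.77). Ebf1 changed sign without vehicle replicate 1 or venetoclax replicate 2. With a sample left out the difference ranged from 0.32 to 1.68 for Trp53, from 0.78 to 2.27 for Cebpb, from 0.63 to 1.31 for Ets1, from 0.48 to 0.91 for Tcf7 and from -2.30 to -1.99 for Spi1. The groups overlapped for Klf2, Trp53, Ctcf, Lef1 and Ebf1. None of these motifs passed an adjusted p of 0.05, and the 95% interval of a motif reached, at the median, 1.47 score units to either side.

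The second comparison asked whether families of motifs, listed before the data were examined, differed together. The median of all motifs was -0.29 with venetoclax relative to vehicle and -0.03 after each sample was centred on its own median, so the list medians that follow are relative to all motifs, while single motifs and counts of positive or negative motifs refer to the difference itself. Of all motifs, 61.3% had a negative difference, so a count near that share gives no direction of a list. Of 34 lists, none passed an adjusted p of 0.05 in camera with an estimated correlation between motifs. The smallest adjusted p was 0.689, and 1 list had an unadjusted p under 0.05. With a preset correlation camera called 10 lists, none of which held with the estimated correlation, and the fry rotation test called 0. The estimated-correlation test rests on 2 residual degrees of freedom and recovered 0 of 3 simulated lists shifted by 3 score units after adjustment. The estimated correlation was above the preset of 0.01 for AP-1 (0.073), Myc, Usf and Hif (0.11), Hox (0.235), IRF (0.245) and forkhead (0.41). It was below the preset for Mef2 (-0.029), retinoid receptors (-0.024), E proteins (-0.019) and Creb and Atf (-0.017). In these lists correlation between motifs does not account for the larger p.

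Motifs of the Myc, Usf and Hif factors, which act in growth, metabolism and hypoxia, had a list median of 1.46. Positive differences were found for 22 of these 25 motifs. The list mean was -0.35 ± 0.12 with vehicle and 0.59 ± 0.22 with venetoclax (SD, n = 2 each). Camera gave an adjusted p of 4.27e-06 with the preset and an adjusted p of 0.689 with an estimated correlation. Of the 25 motifs, 0 passed when adjusted over the list alone and 0 when adjusted over all motifs. The members with the largest differences were Usf1 (2.10), Tfe3 (1.88), Ahr (1.82) and Srebf2 (1.78). The Mef2 list, of muscle and lymphocyte activation factors, had a median of 1.53 with 10 of 13 motifs positive, led by Srf (2.14), a related MADS-box factor. Its median was 0.96 with 1 value per symbol. For this list the adjusted p was 0.0124 with the preset and the adjusted p was 0.689 with an estimated correlation.

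The AP-1 list, of Fos, Jun and Batf factors induced by T cell activation, had a median of 0.97, with 12 of 17 motifs positive. Its members went both ways, with Jdp2 at 1.88 and Fos at 1.82 against Junb at -1.57. The adjusted p went from 0.0269 with the preset to an adjusted p = 0.822 with an estimated correlation. The Creb and Atf list had a median of 1.00 with 15 of 22 motifs positive, among them Creb3 at 1.65, while Atf4 and Atf5 were at -1.23. Camera gave an adjusted p of 0.0338 with the preset and an adjusted p of 0.689 with an estimated correlation. The retinoid, vitamin D and Ppar receptor list had a median of 0.87 with 29 of 41 motifs positive. It was led by Thrb, and Rxra, the shared partner of these receptors, was at -1.80. For this list the adjusted p was 0.00175 with the preset and the adjusted p was 0.689 with an estimated correlation (unadjusted p = 0.045). The list of E proteins and related factors, called the E protein list here, had a median of 0.38 with 25 of 45 motifs positive and 20 negative. Its members furthest from 0 were Myf5 at 2.37, Zeb1 at 2.28, Myf6 at 2.17 and Id2 at 1.95. Camera gave an adjusted p of 0.0338 with the preset and an adjusted p of 0.689 with an estimated correlation. Adjusted over the list alone, 1 AP-1 motif (Fosb) and 2 retinoid receptor list motifs (Thrb and Thra, with the same scores) passed, against 0 adjusted over all motifs. No motif of the Mef2, Creb and Atf or E protein lists passed either way.

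The IRF list, of interferon and lymphocyte differentiation factors, had a median of -0.74, with 8 of 9 motifs negative. Its mean was 0.38 ± 0.55 with vehicle and -0.87 ± 0.60 with venetoclax (SD, n = 2 each). Irf5 was at -2.72 and Irf1 at -1.67. The groups overlapped for Irf5, which scored 0.52 and 2.88 with vehicle and 0.70 and -2.75 with venetoclax. For this list the adjusted p was 0.0338 with the preset and the adjusted p was 0.822 with an estimated correlation. The forkhead list had a median of -0.36 with 132 of 173 motifs negative, which held 71 distinct sets of scores. Its median was -0.71 with 1 value per symbol and -0.61 with 1 entry per distinct set of scores. Its mean was 0.58 ± 0.13 with vehicle and -0.14 ± 0.84 with venetoclax (SD, n = 2 each). Venetoclax replicate 1, at 0.45, was close to vehicle replicate 1, at 0.48, and only venetoclax replicate 2, at -0.74, lay apart from the other 3 samples. The adjusted p went from 0.00175 with the preset to an adjusted p = 0.896 with an estimated correlation. Homeobox motifs of the Hox list had a median of -0.38 with 48 of 61 negative, among them Hoxc11 (-2.42), Hoxa11 (-2.39) and Hoxc9 (-2.31). Camera gave an adjusted p of 0.0104 with the preset and an adjusted p of 0.822 with an estimated correlation. Adjusted over the list alone, 5 forkhead motifs (Foxo1, Foxa1, Foxa2 and the motif shared by Foxf2 and Foxf1), 0 IRF motifs and 0 Hox motifs passed, against 0 adjusted over all motifs.

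The lists that follow were not called by camera with either correlation. The Sox list had a median of -0.51 with 25 of 34 motifs negative, and 4 passed when adjusted over the list alone. These were Sox8, Sox5, Sox18 and Sox7, which have the same scores, at -2.21. The Sox median was -0.85 with 1 value per symbol. The Klf and Sp list had a median of -0.44 with 42 of 54 negative. The Smad list, of TGF-beta signalling factors, had a median of -0.60, a median of -0.39 with 1 value per symbol and a median of 0.12 when each distinct set of scores was counted once. All 7 Egr motifs were negative, with a list median of -0.18, which changed sign without venetoclax replicate 1. Wt1, at -2.77, was the Egr list motif that passed when adjusted over the list alone. The list of Treg factors had a median of -0.22 with 11 of 17 negative, which was -0.57 with 1 value per symbol and -0.38 after quantile normalization. The list of effector Treg and activation factors had a median of 0.33 with 12 of 23 motifs positive. The list of naive and resting T cell factors had a median of -0.05 with 9 of 23 positive. The counts of the Treg list and the naive and resting list were near the share over all motifs, 61.3% negative. Adjusted over the list alone, 1 motif passed in each of these 3 lists, against 0 adjusted over all motifs. It was Foxo1 in the list of Treg factors and in the list of naive and resting T cell factors. The Runx list had a median of 0.69, the p53 list 0.52, the NF-kappaB list 0.51, the steroid receptor list 0.58 and the Gata list 0.39. The STAT list had a median of -0.22, the Tcf and Lef list -0.25, the NFAT list 0.13, the T-box list 0.13, the ETS list 0.06, the E2f list 0.07, the Pou list -0.01 and the Bach, Nfe2 and Maf list 0.21. The steroid receptor list changed sign without venetoclax replicate 2, the STAT list without vehicle replicate 2, the NFAT and ETS lists without vehicle replicate 1, and the Tcf and Lef and E2f lists without vehicle replicate 2 or venetoclax replicate 2. The Pou list and the list of naive and resting T cell factors changed sign without venetoclax replicate 1 among others. The Gata and ETS lists changed sign when only motifs with an SD of at least 1 were kept.

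Lists of other blood lineages, which mark cells that an isolated Treg sample could still hold, did not pass either. The list of B cell factors had a median of 0.22, the list of myeloid factors 0.31, the Cebp list 0.18 and the list of erythroid and megakaryocyte factors 0.11. The first and last of these changed sign without venetoclax replicate 2, the last also without vehicle replicate 1. Spi1, which belongs to the B cell and myeloid lists, was the motif that passed in each when adjusted over the list alone, as Trp63 did in the p53 list. Many of these factors share motifs with T cell factors. The median, the mean and the direction of the camera test differed in sign for the Gata, E2f, B cell and Pou lists. The list means of the vehicle and venetoclax samples did not overlap in 20 of the 34 lists, where chance gives 33.3% of independent lists. The exact permutation test of a list mean cannot go below p = 0.333 with 2 samples against 2.

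List medians moved with the samples and motifs kept. With each sample left out in turn the median ranged from 1.06 to 2.06 for Myc, Usf and Hif; from 0.78 to 2.63 for Mef2; from 0.54 to 1.57 for AP-1; from 0.53 to 1.00 for Creb and Atf; from 0.39 to 0.97 for retinoid receptors; from 0.27 to 0.53 for E proteins; from -1.04 to -0.76 for IRF; from -0.99 to -0.04 for forkhead; from -0.64 to -0.21 for Hox; from -0.63 to -0.41 for Sox; from -0.53 to -0.13 for Klf and Sp; from -0.72 to -0.39 for Smad; from -0.34 to -0.02 for Treg factors; from 0.21 to 0.54 for effector Treg and activation factors; from 0.21 to 1.15 for Runx; from 0.06 to 0.93 for p53; from 0.16 to 0.66 for NF-kappaB; from 0.18 to 0.52 for Gata; from 0.01 to 0.35 for T-box; from 0.02 to 0.55 for Bach, Nfe2 and Maf; from 0.16 to 0.48 for myeloid factors; from 0.10 to 0.38 for Cebp. The SD minimum, which left 357 motifs with a median of -1.29, gave 3.14 for AP-1; 2.62 for Creb and Atf; -0.86 for IRF; -0.66 for ETS; -0.23 for Gata; -0.25 for forkhead; -0.23 for Klf and Sp; 3.24 for E proteins; 3.04 for Myc, Usf and Hif; 2.66 for retinoid receptors; 2.63 for Mef2; 2.82 for myeloid factors; 2.82 for Cebp; -0.28 for Pou; -0.69 for Sox; -0.75 for Hox; -0.37 for Treg factors; 3.33 for effector Treg and activation factors; -0.40 for naive and resting T cell factors. With 1 value per symbol the median was 0.35 for steroid receptors, 0.27 for T-box and 0.02 for E2f, and with 1 entry per distinct set it was 0.34 for steroid receptors; 0.08 for T-box; 0.10 for Bach, Nfe2 and Maf; 0.15 for myeloid factors; 0.01 for Cebp. None of these settings gave a list past the threshold in camera with an estimated correlation. The SD minimum selects motifs by their variation over the same samples and so favours large differences. Their SD over motifs was 1.69, against 1.07 for all motifs. The list medians under that setting are relative to -1.29, so their larger size is no support for a list.

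**Figure D2:**
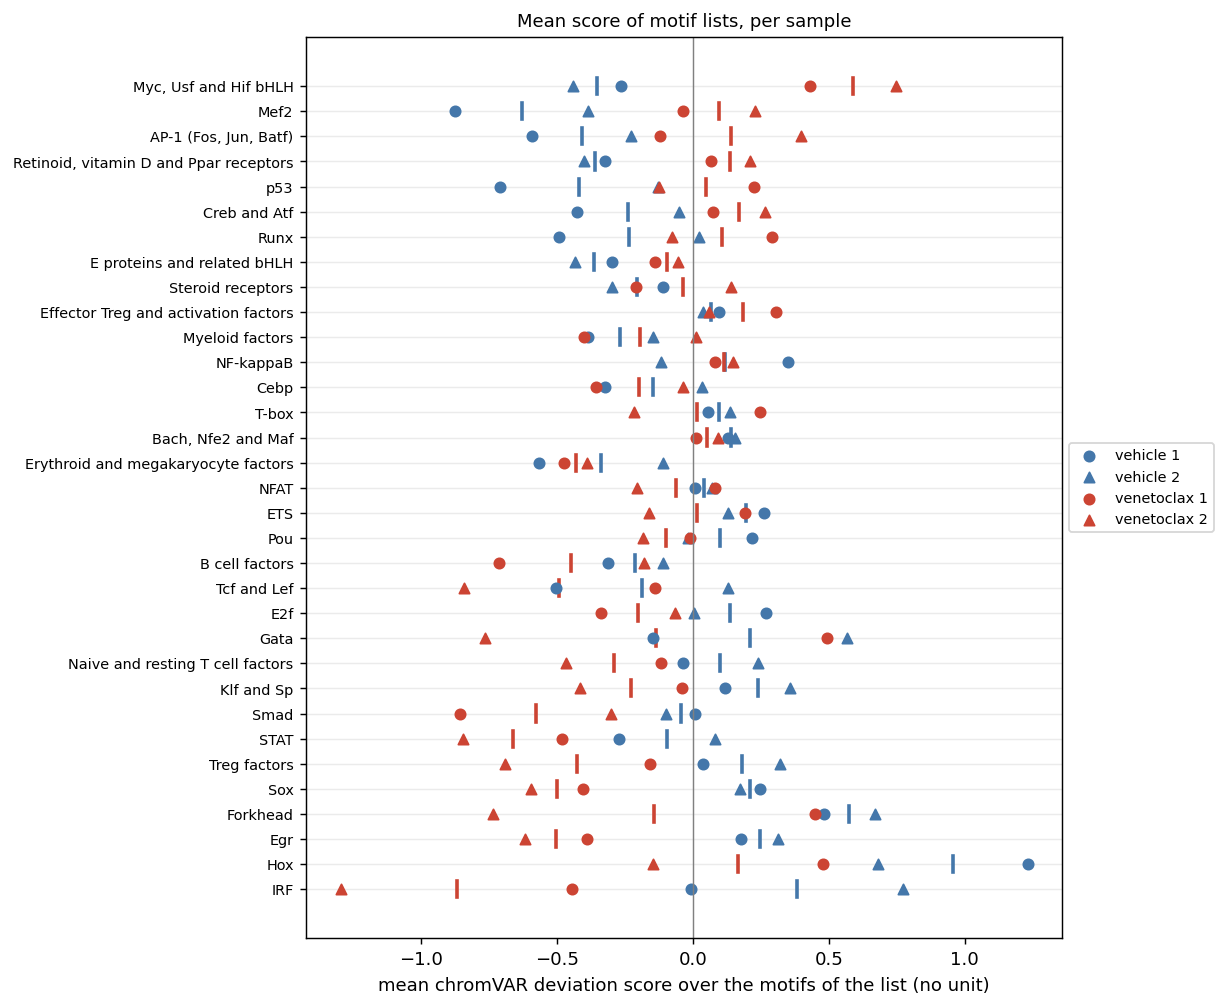
Mean deviation score of motif lists (no unit, horizontal axis) in each sample, with the lists on the vertical axis, circles for replicate 1, triangles for replicate 2, vehicle in blue, venetoclax in red and a bar at each group mean. The Myc, Usf and Hif list lies at -0.27 and -0.44 with vehicle and at 0.43 and 0.75 with venetoclax, while the forkhead list is low only in venetoclax replicate 2; no list passed the main test.

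The third comparison asked how alike the samples were. Across motifs, which are not independent replicates, the vehicle samples correlated with r = 0.60 and the venetoclax samples with r = 0.09. Venetoclax replicate 1 correlated with vehicle replicate 1 (r = 0.57) about as strongly as the vehicle samples did with each other. Its correlation with vehicle replicate 2 was lower (r = 0.38). Venetoclax replicate 2 was opposed to vehicle replicate 2 (r = -0.74) and less so to vehicle replicate 1 (r = -0.18). The difference from the vehicle mean had an SD over motifs of 0.84 in venetoclax replicate 1 and 1.53 in venetoclax replicate 2. The differences of the venetoclax samples correlated with r = 0.61. Simulated unchanged samples set against a shared vehicle mean gave 0.33, with an SD of 1 in each sample. There the shared vehicle samples added a covariance of 0.50. The real differences had a covariance of 0.78, and the vehicle samples' own spread adds 0.18 of it, so the simulated 0.33 is from another setting. With a separate vehicle sample for each venetoclax sample, r was 0.31 or 0.50, depending on the assignment.

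**Figure D3:**
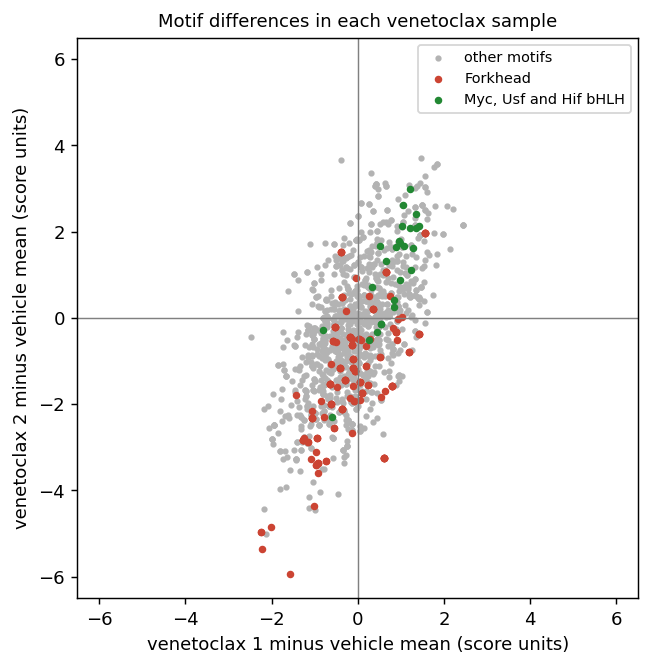
Difference of each motif from the vehicle mean in venetoclax replicate 1 (horizontal axis, score units) and replicate 2 (vertical axis, score units), with red points for the forkhead list, green for the Myc, Usf and Hif list and grey for other motifs. The spread is wider in replicate 2 (SD 1.53) than in replicate 1 (SD 0.84), and the forkhead points lie mostly below 0 in replicate 2.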

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

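The share of motifs at an unadjusted p, the relative list medians, the 1 entry per distinct set of scores and the score with an SD of 1 were chosen after seeing the data. The count of 0 motifs past the adjusted threshold was also 0 under the block, the scalings, the SD minimum, the merging of entries, the ordinary model, the score with an SD of 1 and a threshold of 0.01. It was 6 at a threshold of 0.10 and 74 with a trended and robust variance. Leaving out a sample gave 0 to 337, the latter without venetoclax replicate 1; that test assumes that the lone sample varies like the vehicle samples. The 18.3% of motifs at an unadjusted p under 0.05 became 7.43% with the replicate block, 6.84% with an ordinary model, 8.02% with a score SD of 1 and 3.49 to 37.6% without a sample (lowest without vehicle replicate 2, highest without venetoclax replicate 1). Other settings gave 15.1 to 20.7%. Same-numbered samples deviated with r = -0.27 and the labels give no shared origin, so the numbers are not shown to pair; the block leaves 1 degree of freedom per motif. The 0 lists became 10 with the preset correlation and stayed 0 under the other settings run. Depth could not be examined.

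Of 41 named motifs, 8 changed sign, all in fits without a sample. The ranges were -1.97 to 0.32 for Ctcf, -1.32 to 0.14 for Lef1, -1.12 to 0.098 for Stat5b, -0.53 to 1.43 for Ebf1, -0.075 to 0.88 for Runx1, -0.057 to 0.66 for Rela, -0.24 to 0.46 for Bach2 and -0.24 to 0.33 for Tbx21. Relative list medians without a sample ranged from -0.097 to 0.13 for NFAT, -0.73 to 0.085 for STAT, -0.59 to 0.24 for Tcf and Lef, -0.0063 to 0.11 for ETS, -0.59 to 0.067 for Egr, -0.23 to 0.62 for steroid receptors, -0.29 to 0.40 for E2f, -0.28 to 0.48 for B cell factors, -0.37 to 0.48 for erythroid and megakaryocyte factors, -0.25 to 0.36 for Pou and -0.13 to 0.077 for naive and resting T cell factors. Pou became 0.0029 after division by the SD, 0.0099 after quantile normalization and 0.075 with 1 value per symbol. The SD minimum gave -0.66 for ETS and -0.23 for Gata. ETS was -0.25 with 1 value per symbol and -0.26 with 1 entry per distinct set; naive and resting T cell factors were 0.018 and 0.11 in these settings, and Smad 0.12 in the latter. The cause was not tested.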

Other observations

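Except for the centring test, the tests in this part were chosen after the values they rest on, or closely related values, had been seen, as were the 17 further motif lists. Motifs of Myb factors, regulators of blood cell progenitors, had positive differences in 4 of 4 cases, with a median of 2.12 relative to all motifs and a list mean of -0.92 ± 0.15 with vehicle and 0.72 ± 0.88 with venetoclax (SD, n = 2 each). Motifs of the Pitx and Otx homeodomain factors had negative differences in 10 of 11 cases, with a median of -1.67 relative to all motifs, and those of Pbx and Meis in 13 of 14, with a median of -1.13. Hes and Hey motifs, of Notch targets, had a median of -0.87 and Rfx motifs, of a family with factors acting on MHC class II genes, a median of -0.56. Zic and Gli motifs had a median of -0.33 and Dmrt motifs 1.03. Further lists were at 0.88 for Ikzf and Gfi1; 0.71 for Nkx; 0.61 for Tfap2; 0.53 for Nfi; 0.50 for Neurod, Neurog and Atoh; 0.32 for Irx; 0.21 for Lhx; 0.07 for Hsf; 0.04 for Nr2 receptors, all relative to all motifs. No list of the 17 passed camera with an estimated correlation (smallest adjusted p = 0.687), and the lists were picked from the same scores.

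The difference between the groups was largest in venetoclax replicate 2, whose scores were opposed to those of vehicle replicate 2. A shift of all its scores is argued against: after each sample was centred on its median 215 motifs had an unadjusted p under 0.05, against 246 before. An event particular to that sample, such as its preparation or cell content, cannot be told apart from a response that differed between mice. With a separate vehicle sample for each, the venetoclax differences correlated at 0.309 or 0.502 across motifs. The difference between the vehicle samples and that between the venetoclax samples, which hold no treatment contrast, correlated at -0.268, where the sign depends on the order of the samples; 0.309 is close to this in size and 0.502 is above it. The test was first set to count 0.309 as above its bound of 0.3, and the condition to exceed it by the bootstrap SE of 0.028 was added afterwards. That bootstrap drew transcription factor symbols and takes them as independent, which they are not.

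Of the 3 ways to split the 4 samples into pairs, 1 gave as many as 246 motifs at an unadjusted p under 0.05, the split by treatment, and the highest of the others gave 41. With 3 splits the share cannot fall under 0.05. An effect of venetoclax, the difference the design names, remains open. The forkhead, Hox and Sox lists, whose motifs are rich in A and T, had medians below that of all motifs. None passed camera with an estimated correlation. The low medians could follow from a trend with base content. These lists were chosen after their medians had been seen. Not all lists of such motifs were low: Mef2 lay at 1.53, Pou at -0.01 and Lhx at 0.21 relative to all motifs. Of the GC-rich lists, Klf and Sp lay at -0.443 relative to all motifs (SE 0.19 over distinct sets of scores), Egr at -0.178 (SE 0.43) and E2f at 0.069 (SE 0.26). As these lists did not lie on 1 side beyond their error, the trend is neither excluded nor shown. Their SEs take the sets of scores as independent, which they are not. After a first reading of Klf and Sp alone, all 3 lists were required. The base content of each motif was not analysed here.

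On average the scores varied over the 4 samples by less than a variance of 1. In a chi-square test against a score with a variance of 1, 1 of 976 distinct motif patterns passed the adjustment, the forkhead motif of Foxa1 (SD over the 4 samples 2.82, adjusted p = 0.0271), chosen after its value was seen. The patterns were divided into this pattern and the others after that result. Sampling of the background peaks alone is argued against for that pattern. Of the other 975 patterns, 3.59% had an unadjusted p under 0.05, but this share decides nothing. The variance over the 4 samples averaged 0.763 (SE 0.027 over patterns, median 0.50). That SE takes the patterns as independent, which they are not. If a variance of 1 is too large for these scores, it lowers the share. With the same SD of 1 per sample, the treatment contrast gave 8.02% of all motifs at an unadjusted p under 0.05. Sampling of the background peaks alone stays open for these patterns. The variance test does not use the treatment groups, takes the scores to be z-scores and has 3 degrees of freedom per motif.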
